A study of Mus musculus with 52 samples.

How the data were processed

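The series holds 52 mouse samples, of which 10 were analysed here: 6 RNA-seq libraries and 4 whole-genome bisulfite sequencing (WGBS) libraries. The 42 ATAC-seq and ChIP-seq samples were not analysed here. The RNA libraries came from Epcam-sorted midgut epithelium of wild-type CD1 embryos at E11.5 (embryonic day 11.5), and from epithelium released with EDTA from the proximal intestine of adult Eed F/F; Villin-Cre mice of mixed B6;129 background, taken 11 or 14 days into tamoxifen treatment. Tamoxifen activates the inducible Cre recombinase in intestinal epithelium, which is meant to remove Eed, a subunit that Polycomb repressive complex 2 (PRC2) needs to methylate histone H3 at lysine 27. These adult samples are called Eed-null below, as their labels call them knockouts. There were 2 libraries per RNA group, which the labels call biological replicates. Nothing in the labels says that each came from a separate animal, so every p-value measures the spread between these libraries only. The WGBS libraries came from E12.5 and E16.5 midgut epithelium, wild-type adult intestinal epithelium and wild-type macrophages, with 1 library per condition. For the macrophage library the labels give villus cells as the source, while the extraction text names cultured C-Kit-positive bone marrow cells. It is treated here as macrophage DNA because its title says so.

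The deposited RNA table holds counts, whole numbers of reads per gene symbol for 24014 genes and 12 columns, with no normalization. Of its columns, 6 carry names that match labelled samples and were used, and the other 6 columns were not used here. Per the submitters' processing notes the tools included STAR 2.5.3a and DESeq2 with the mm9 genome build. The program that counted reads, the annotation and the treatment of reads that map to several places are not stated. Embryonic RNA was made into libraries with a SMARTer low-input kit and adult RNA with a TruSeq kit, so kit, read length, strain, sorting and age all differ together between E11.5 and the Eed-null groups and cannot be told apart in these comparisons. The deposited WGBS tables hold, for each cytosine position, the percent of calls that were methylated and the percent that were converted, per the file headers. The notes name Bismark 0.13.1 and Bowtie2 2.1.0 with mm9. The tables give neither the number of reads nor the strand, so the depth behind each level is unknown, and no interval or test that needs read counts was computed. The Fisher tests, read minimums and thinning planned for these data before the data were examined could therefore not be run. The plan asked for 3 positions and 20 calls per tile; a minimum number of measured sites was set in its place once the files had been seen, and the same was done for regions.

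The deepest RNA library held 27.7 and the shallowest 19.2, in units of 1e6 counts. Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3: genes were filtered with filterByExpr, libraries were scaled with TMM factors, and quasi-likelihood F-tests were adjusted by the Benjamini-Hochberg method. Day 14 was compared with day 11 on the 4 adult libraries at an adjusted p under 0.05. E11.5 was compared with each Eed-null group in 1 fit of all 6 libraries at an adjusted p under 0.05 and at least a 2-fold change. Levels per library are counts per 1e6 counts (CPM) over TMM-scaled totals of all 6 libraries, and are given as mean ± SD with n = 2. They were first computed over raw totals, and the change to TMM-scaled totals was made after the values had been seen, because raw CPM and fitted fold changes differed; the overlap between libraries in the choice of named genes uses the scaled values. A fold change against a group with no count in either library is given as a lower bound, with 3 counts set as the floor of each library. Where a group held 1 to 3 counts in all, the ratio of counts is given with its exact 95% binomial (Clopper-Pearson) interval. Such intervals and floors cover counting error only, and PCR duplicates could not be removed.

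Before the data were examined, 34 gene lists with 815 genes were fixed, covering Polycomb complexes and their textbook targets, developmental genes, intestinal cell types, growth, stress, immune and metabolic programmes, and cell types that an epithelial preparation could carry along. Each list with at least 3 tested members was tested with camera at a preset correlation of 0.01 between genes and adjusted over lists, and the test was repeated with a correlation estimated from the data. With an estimated correlation no list passed in any of the 3 RNA comparisons. That form of the test rests on the residual degrees of freedom. These were 2 for day 14 against day 11 and 3 for the comparisons with E11.5, so few lists could pass it. A list that did not pass it is therefore not shown to be unchanged. The named genes were also chosen by a rule fixed in advance: PRC2 genes, the 12 largest rises and 12 largest falls among genes past the test with a mean of at least 5 CPM in the higher group and no overlap between libraries, and up to 4 members of each list with the smallest adjusted p. Predicted genes, Xist and Y-linked genes were counted but left out of the largest changes, and genes known only by a clone or locus number were left out as well, which the rule had not foreseen. Genes higher or lower in E11.5 than in the mean of both Eed-null groups were tested as sets in the day 14 against day 11 contrast, which is orthogonal to the first. The difference without any change was taken from 30 simulated data sets, which do not cover the spread between libraries.

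Positions of a WGBS file that belong to the same CpG were merged into 1 site. Tiles of 1000 bp with at least 5 measured sites in both libraries of a pair were compared, and a difference of at least 30 percentage points was counted. Each tile was also split into its odd and even measured sites, which gives a measure of the noise within 1 library. Low-methylated regions were runs of at least 4 sites with a running mean over 3 sites under 50%, gaps of at most 500 bp and a mean under 50%. Runs of 30 or more sites were called unmethylated regions. Low-methylated E12.5 regions with at least 4 measured sites in every library and a macrophage level of 50% or more formed the set whose level was read in E16.5 and adult epithelium. The background was the same regions shifted by 20000 bp, and the mirror set was the low-methylated macrophage regions that were methylated at E12.5. Shares of regions are given with exact Clopper-Pearson 95% intervals, which treat regions as independent although they are not replicates, and with the SD over the 19 autosomes. The annotation at hand was of the assembly GRCm38.p6 and the files are on mm9, so promoters were not analysed, tiles and regions carry mm9 coordinates without a gene, and gene positions are given on GRCm38.p6. Of the 24014 gene symbols, 22934 were found directly in that annotation, 961 through older names and 119 were not found.

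The procedure was tested on simulated data with changes planted at 100 genes per fold and comparison. For day 14 against day 11, 2.0% of genes with a 2-fold change and 73.0% with a 4-fold change were found, and 4 of 13813 unchanged genes were called. For E11.5 against day 11 the shares were 4.0% at 2-fold and 46.0% at 4-fold with 8 of 15095 unchanged genes called, and for E11.5 against day 14 they were 5.0% and 64.0% with 11 of 14966. No list without a planted change was called, but simulated genes were drawn independently of each other, so this does not test the preset correlation. In simulated methylation data 600 of 600 planted low regions were found, and 60.5% of regions were read as kept low where 60.5% had been planted. All planted regions had the same low level against the same background level, at 5 simulated calls per site. The depth of the real libraries is unknown, so this recovery does not measure the error of the real shares. A 2-fold difference was thus seldom detectable with 2 libraries per group.

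Alternatives were RLE size factors, no filter on low counts, the DESeq2 1.42.0 Wald test, other sets of libraries, other fold limits, the replicate number as a block, each library left out in turn, and other limits on tiles and regions. After the data had been seen, fits with a trend of log2 CPM on genomic gene span removed, fits without genes that have a named pseudogene copy, fits without ribosomal protein and non-epithelial lists, and some limits on site numbers were added. A named copy is an annotated pseudogene that carries the gene's symbol with the ending -ps, with or without a number. Copies under other names were not counted. Methylation tables were handled in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.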

Results

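RNA was measured in 3 groups of 2 libraries: E11.5 midgut epithelium, and adult Eed-null intestinal epithelium at day 11 and at day 14 of tamoxifen treatment. The E11.5 libraries held 24319967 and 27737012 counts, the day 11 libraries 20046945 and 19259493, and the day 14 libraries 19722369 and 19155508. DNA methylation was measured by WGBS in 1 library each of E12.5 epithelium, E16.5 epithelium, adult epithelium and macrophages, with no replicates. The E12.5 library covered 16278295 CpG sites, the E16.5 library 16607692, the adult library 20829065 and the macrophage library 17006566, at an unknown read depth. Across genes, which are not independent replicates, log CPM correlated at 0.945 between the E11.5 libraries, 0.963 between those of day 11 and 0.969 between those of day 14. CPM are given as mean ± SD with n = 2, and adjusted p-values of genes are from edgeR quasi-likelihood tests with Benjamini-Hochberg adjustment.

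**Figure D1:**
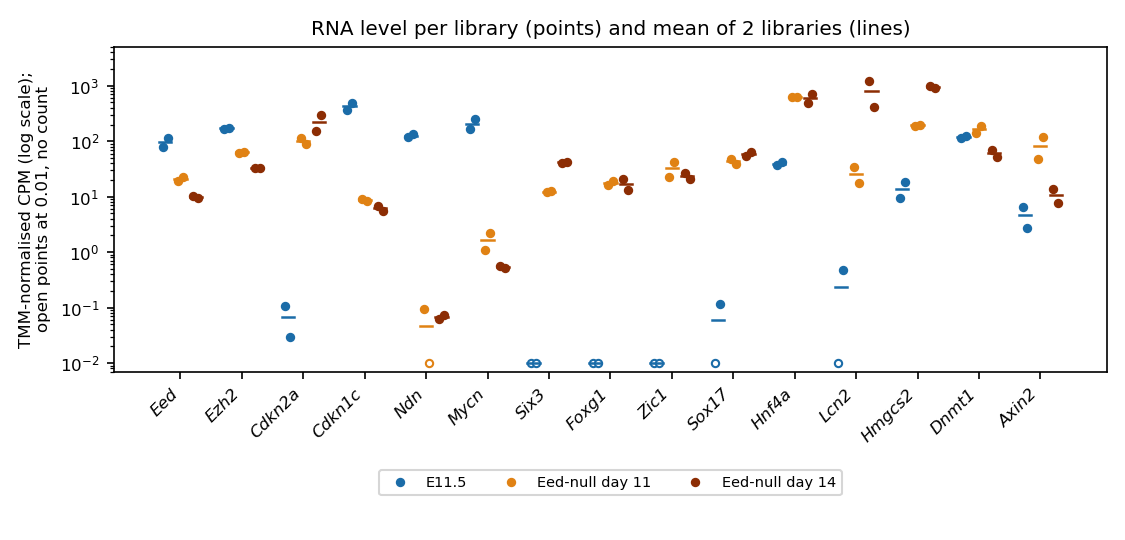
Levels of 15 genes in each of the 6 RNA libraries, in CPM on a log axis, with a point per library, a line at the group mean and an open point at the lower edge for no count. Eed lay at 96.3 CPM in E11.5, 21.0 at day 11 and 9.88 at day 14.

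The comparison of day 14 with day 11 asked what else changes between these days of tamoxifen treatment. Single genes of secreted defence (Lcn2), ketone synthesis (Hmgcs2) and isoprenoid synthesis (Idi1) rose, and single genes of DNA methylation upkeep (Hells), DNA replication (Cdc6) and enterocyte regulation (Hnf4g) fell. Most genes of the lists that hold them did not pass. Lcn2, which encodes a secreted protein that binds bacterial iron carriers, rose from 25.8 ± 11.6 to 816 ± 579.8 CPM (log2 fold change 4.96, SE 0.66, adjusted p = 0.0137). Hmgcs2, the mitochondrial enzyme of ketone body synthesis, rose from 194 ± 5.21 to 953 ± 71.8 CPM (log2 fold change 2.27, SE 0.35, adjusted p = 0.0221). Hells, a chromatin remodeller needed for DNA methylation, fell from 74.0 ± 1.88 to 15.9 ± 6.20 CPM (log2 fold change -2.25, SE 0.35, adjusted p = 0.0222).

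Of 14245 genes tested, 429 rose and 379 fell, and 4419 had an unadjusted p under 0.05. With a trend on gene span removed, 289 rose and 157 fell. Risen genes had a median genomic span of 8.6 kb and fallen genes of 35.4 kb, against 22.1 kb in all tested genes. Per 10-fold span, log2 CPM changed by -0.21 to -0.61 from a day 11 to a day 14 library. Between the day 14 libraries it changed by -0.28, from replicate 1 to replicate 2. The calls thus partly followed gene span. Without day 14 replicate 2 the counts were 210 and 49, without day 14 replicate 1 they were 1194 and 1186, without day 11 replicate 1 they were 728 and 761, and without day 11 replicate 2 there were 262 rises. Of the 77 genes named by rule that passed, 33 passed in each of these 4 fits, among them Lcn2, Saa1, Nupr1, Hmgcs2, Idi1, Hells, Cdc6, Hnf4g, Dcn, Col3a1 and Lyz2. Xist and the Y-linked genes, chosen after their values were seen, parted the days: Xist lay at 0.387 ± 0.349 CPM at day 11 and at 569 ± 123 CPM at day 14, while Ddx3y lay at 32.1 ± 3.99 CPM at day 11 and had no count at day 14. Both day 11 libraries thus had the RNA pattern of male tissue and both day 14 libraries that of female tissue. The day of treatment and sex, as read from RNA, cannot be told apart in this comparison.

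Eed itself, on chromosome 7 from 89954654 to 89980976, measured 21.0 ± 2.67 CPM at day 11 and 9.88 ± 0.532 CPM at day 14, a difference that did not pass (log2 fold change -1.11, SE 0.36, adjusted p = 0.0946). Eed RNA was thus still counted, and with no wild-type adult library and no value for the deleted part of the gene, its loss was not verified here. Ezh2, the catalytic subunit of PRC2, measured 63.2 ± 2.34 and 32.6 ± 0.495 CPM and did not pass either (adjusted p = 0.0674). None of the 11 PRC2 genes passed with edgeR over all genes, and 2 had lower levels at day 14 when adjusted over the list alone. Among 19 components of Polycomb repressive complex 1, Rybp rose (log2 fold change 1.71, SE 0.30, adjusted p = 0.0289) and Cbx2, which binds methylated H3 lysine 27, fell (log2 fold change -2.14, SE 0.48, adjusted p = 0.0477). Adjusted over the list alone, 4 rose and 3 fell, and the list's median (-0.02) and mean (0.07) differed in sign. Rybp is among the genes with a named pseudogene copy, which as a class were higher at day 14. The Rybp call was lost without day 11 replicate 1 (adjusted p = 0.0545) and without day 11 replicate 2 (adjusted p = 0.0509), and the Cbx2 call without day 11 replicate 2 (adjusted p = 0.206) and without day 14 replicate 2 (adjusted p = 0.115).

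Few textbook Polycomb targets passed between the days, at a size of experiment that found 2.0% of planted 2-fold changes. Of 86 developmental transcription factors 1 rose over all genes, none rose adjusted over the list alone, and none fell: Six3, a forebrain and eye regulator on chromosome 17, went from 12.3 ± 0.157 to 41.9 ± 1.36 CPM (log2 fold change 1.74, SE 0.31, adjusted p = 0.0304). Its call was lost without day 11 replicate 2 (adjusted p = 0.0687) and without day 14 replicate 2 (adjusted p = 0.0620). Log2 fold changes of the list ran from -3.24 to 2.16, so genes that did not pass are not shown to be unchanged. None of 36 Hox genes, 29 Fox genes, 6 inhibitors of cyclin-dependent kinases (CDK) or 23 embryonic growth and imprinted genes passed, over all genes or adjusted over the list alone. Cdkn2a, which encodes the cell cycle brakes p16 and p19, measured 102 ± 19.2 CPM at day 11 and 224 ± 104 CPM at day 14 (adjusted p = 0.106).

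Of 16 tested genes for secreted antimicrobials and acute response proteins, 3 rose, and 10 rose when adjusted over the list alone. Beside Lcn2, Saa1, an acute phase lipoprotein, rose from 1.31 ± 0.395 to 28.3 ± 23.1 CPM, and Reg3a, a bactericidal lectin, rose from 2.16 ± 1.77 to 20.6 ± 10.98 CPM, a call lost without day 14 replicate 2 (adjusted p = 0.1497). The list's median log2 fold change was 2.26 (camera adjusted p = 1.1e-05, and adjusted p = 0.926 with an estimated correlation). Over the same days leukocyte genes had a median of -2.15 and macrophage genes of -3.79. Nupr1, a stress-induced chromatin protein in the Paneth cell list, rose from 62.4 ± 22.7 to 518 ± 44.4 CPM. In the goblet cell list none of 14 genes passed with edgeR over all genes and 2 rose when adjusted over the list alone, with a median of 0.67 (camera adjusted p = 0.0357, and adjusted p = 0.926 with an estimated correlation). Its call was also lost with a trend on gene span removed (adjusted p = 0.1505). The interferon-stimulated list gave a median of 0.54 with none of 35 genes passing (camera adjusted p = 0.0449, and adjusted p = 0.968 with an estimated correlation), a call also lost with the span trend removed (adjusted p = 0.111).

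Fatty acid oxidation genes and targets of the lipid sensor PPAR included 4 rises among 20 genes, and 5 rises with 1 fall when adjusted over the list alone. They were Hmgcs2, Hadhb of the mitochondrial trifunctional protein, which also has a named pseudogene copy, the lipid droplet protein gene Plin2, which went from 110 ± 41.8 to 391 ± 1.48 CPM, and the acyl-CoA thioesterase gene Acot1. The median was 0.74 (camera adjusted p = 0.00319, and adjusted p = 0.926 with an estimated correlation). Idi1, an isomerase of isoprenoid and cholesterol synthesis, rose from 17.6 ± 7.41 to 206 ± 41.3 CPM, while Stard4, a sterol carrier, fell from 98.1 ± 17.3 to 28.1 ± 9.98 CPM. Of 40 enterocyte genes 3 rose and 3 fell, over all genes and adjusted over the list alone. Apoa4 and Apoa1, which encode apolipoproteins of chylomicrons, rose to 2553 ± 460.9 and 1589 ± 384 CPM, and Enpep, a brush border peptidase, fell from 75.4 ± 0.199 to 22.4 ± 4.04 CPM. Without day 14 replicate 2 the calls were lost, by adjusted p, of Hadhb (0.0501), Plin2 (0.0747), Acot1 (0.109), Stard4 (0.0780), Apoa4 (0.0846), Apoa1 (0.0907) and Enpep (0.0548). Without day 11 replicate 2 those of Hadhb (adjusted p = 0.111), Plin2 (adjusted p = 0.111), Acot1 (adjusted p = 0.230) and Stard4 (adjusted p = 0.0568) were lost, and without day 11 replicate 1 those of Acot1 (adjusted p = 0.0558) and Apoa4 (adjusted p = 0.0519).

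Of 15 genes of the DNA methylation machinery 4 fell: Hells, Uhrf1, which brings the maintenance methyltransferase to new DNA, Dnmt1, that methyltransferase, and Tet1, which oxidises methylated cytosine. Dnmt1 went from 164 ± 36.2 to 60.3 ± 11.3 CPM and Uhrf1 from 78.0 ± 10.97 to 29.3 ± 2.31 CPM. Adjusted over the list alone 6 fell and 1 rose, and the median was -0.97 (camera adjusted p = 0.0164, and adjusted p = 0.926 with an estimated correlation). The list's call was also lost with the span trend removed (adjusted p = 0.0590). Of 39 proliferation genes Cdc6, which loads the replicative helicase, and Mcm5, part of that helicase, fell, with 9 falls and 2 rises adjusted over the list alone. Cdc6 fell to 2.86 ± 0.498 CPM (log2 fold change -2.83, SE 0.42, adjusted p = 0.0198), and the list's median was -0.51 (camera adjusted p = 0.00369, and adjusted p = 0.926 with an estimated correlation). In the stem cell list of 20 genes Axin2, a target of Wnt signalling, and Cdca7 fell and Prom1 rose, with a median of -0.79 (camera adjusted p = 0.0287, and adjusted p = 0.968 with an estimated correlation), and with the span trend removed this list's call was lost too (adjusted p = 0.111). Adjusted over the list alone, 4 fell and 1 rose. Hnf4g, an enterocyte transcription factor, fell from 31.4 ± 0.524 to 5.86 ± 0.163 CPM, and Nr5a2, a nuclear receptor of crypt cells, fell from 19.3 ± 1.08 to 4.46 ± 0.991 CPM, while Tff2, a stomach peptide, rose. Without day 14 replicate 2 the calls were lost, by adjusted p, of Uhrf1 (0.0921), Dnmt1 (0.134), Tet1 (0.186), Mcm5 (0.140), Axin2 (0.0725), Cdca7 (0.134), Prom1 (0.101), Nr5a2 (0.0868) and Tff2 (0.133). Those of Uhrf1 (0.140), Dnmt1 (0.133), Tet1 (0.153), Mcm5 (0.166), Cdca7 (0.193), Prom1 (0.132) and Nr5a2 (0.0620) were lost without day 11 replicate 2. Mcm5 (adjusted p = 0.0605) and Prom1 (adjusted p = 0.0888) were also lost without day 11 replicate 1, and Tet1 without day 14 replicate 1 (adjusted p = 0.0748).

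The mesenchyme, macrophage, leukocyte and endothelium lists were lower at day 14 at the preset correlation only. Of 17 mesenchyme genes 10 fell, and 12 fell when adjusted over the list alone, with a median of -3.92, or -3.46 with genes without a count at their bound (camera adjusted p = 3.9e-08, and adjusted p = 0.926 with an estimated correlation). Dcn, a matrix proteoglycan, went from 16.0 ± 9.42 to 0.163 ± 0.126 CPM. Of 18 macrophage genes 8 fell, and 14 adjusted over the list alone, with a median of -3.79 (camera adjusted p = 1.1e-07, and adjusted p = 0.926 with an estimated correlation); Lyz2, lysozyme of myeloid cells, went from 40.9 ± 24.2 to 2.46 ± 1.60 CPM. Of 12 leukocyte genes 3 fell, and 5 adjusted over the list alone, with a median of -2.15 (camera adjusted p = 0.00161, and adjusted p = 0.926 with an estimated correlation). Of 11 endothelial genes 2 fell, and 8 adjusted over the list alone, with a median of -4.06 (camera adjusted p = 7.5e-04, and adjusted p = 0.926 with an estimated correlation). Day 11 replicate 1 carried more of this RNA than replicate 2: Igj, the joining chain of secreted antibodies, stood at 485 and 58.5 CPM, and Ptprc, the pan-leukocyte gene, at 20.9 and 5.26 CPM. Summed over the list, macrophage genes stood at 847 and 223 CPM at day 11 and at 444 and 144 CPM at day 14, so the days overlapped. Endothelium sums overlapped too, at 224 and 69.3 CPM against 68.1 and 72.4 CPM. Leukocyte and mesenchyme sums did not overlap. The Ptprc call was lost without day 11 replicate 1 (adjusted p = 0.0659) and without day 14 replicate 2 (adjusted p = 0.133). Epcam, chosen after its values were seen as a gene of epithelial cells, lay at 974 ± 125 CPM at day 11 and 1193 ± 228 CPM at day 14.

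Ribosomal protein genes formed the list with the smallest camera p-value: 10 of 41 rose, and 35 when adjusted over the list alone, with a median of 1.66 (camera adjusted p = 2.4e-22, and adjusted p = 0.926 with an estimated correlation). Rpl27 went from 145 ± 20.5 to 852 ± 128 CPM and Rps28 from 143 ± 9.69 to 944 ± 386 CPM. Genes that have a named pseudogene copy, 31 of these 41 among them, had a median log2 fold change of 1.14 over 320 genes, against -0.05 over the 13925 others, and made up 21.4% of risen genes against 2.2% of tested genes. Without them 260 genes rose and 206 fell, and with a trend on gene span also removed 164 rose and 72 fell. Several of the largest rises started from almost no counts: Zfp488 was at least 355-fold higher at day 14 and Olfr613 at least 335-fold higher, and Sec61g, a subunit of the protein channel of the endoplasmic reticulum, went from 0.693 ± 0.275 to 200 ± 48.3 CPM. Sumo2, a protein modifier that most cells express, went from 0.391 ± 0.0410 to 113 ± 46.9 CPM, and lay at 4.21 CPM in E11.5. Olfr613, Psg23, Vmn1r58 and Tyr had no count at day 11, and Mir6236, Snora61, Snord12 and Snord96a had none at day 14. Mir6236 lay at a mean of 99.8 CPM in E11.5. Whether such genes were counted differently in the day 14 libraries was not tested gene by gene. Among annotated pseudogenes, 10 stood at 10 CPM or more at day 14 and under 1 CPM at day 11, against 0 in the other direction. A difference in counting is thus possible, and these fold changes may not reflect RNA levels. Among the largest falls were the small RNA genes Mir6236, at least 284-fold lower, and Snora61, at least 30.7-fold lower, and the endothelial receptor gene Kdr, at least 35.7-fold lower, whose call was lost without day 14 replicate 2 (adjusted p = 0.0898).

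**Figure D2:**
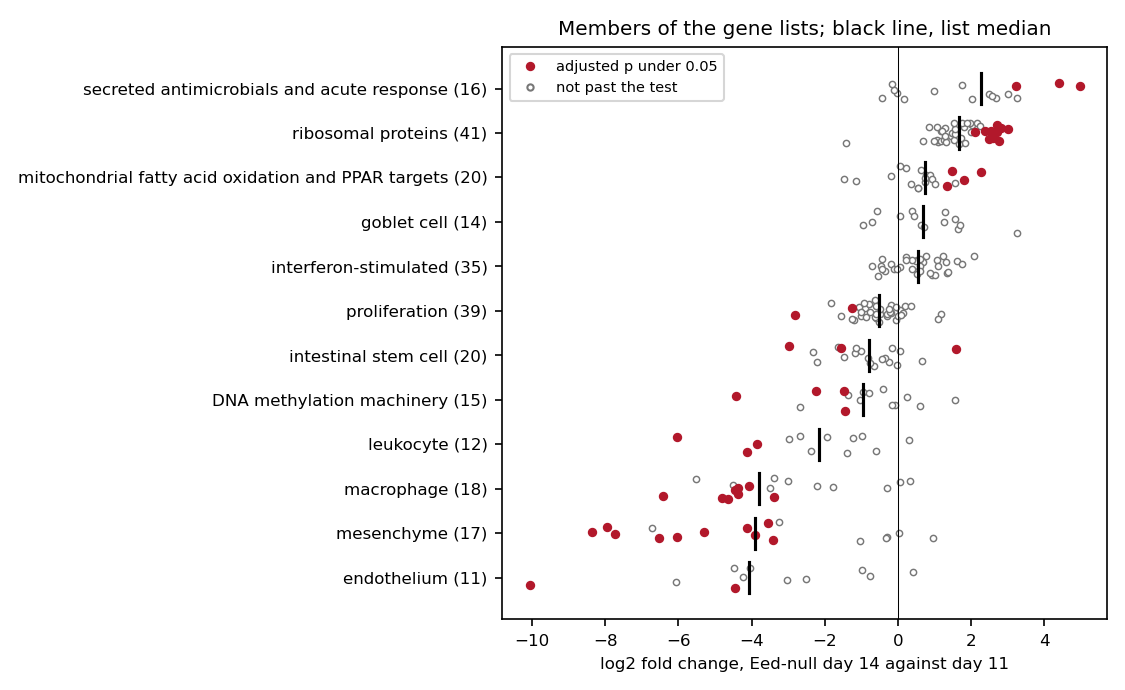
Log2 fold change of day 14 over day 11 for each member of the 12 lists that passed camera at the preset correlation, with a filled red point for an adjusted p under 0.05, an open point otherwise and a black line at the median. The medians run from -4.06 for endothelium to 2.26 for secreted antimicrobials.

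The comparisons of E11.5 with Eed-null adult epithelium asked how far the adult cells labelled as Eed knockouts stand from the embryonic state. Of 25 embryonic growth and imprinted genes 19 were higher in E11.5 than at day 11, and of 40 enterocyte genes 34 were lower, while developmental transcription factors went both ways, with 20 higher and 35 lower of 97. Ndn, an imprinted growth regulator on chromosome 7, lay at 125 ± 10.8 CPM in E11.5 and at 0.0467 ± 0.0661 CPM at day 11 (ratio of counts 2740.1, interval 758 to 22630.0). Mycn, a growth-promoting transcription factor of embryonic tissues, lay at 207 ± 59.3 CPM in E11.5 against 1.65 ± 0.810 CPM at day 11 (log2 fold change 6.97, SE 0.49, adjusted p = 3.7e-05). Cdkn2a, a textbook Polycomb target on chromosome 4 from 89274473 to 89294619, lay at 0.0677 ± 0.0544 CPM in E11.5 and at 102 ± 19.2 CPM at day 11 (log2 fold change -10.50, SE 0.66, adjusted p = 3.0e-05).

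Of 15615 genes tested, 3455 were higher and 3924 lower in E11.5 than at day 11, and 3828 were higher and 4126 lower than at day 14. An unadjusted p under 0.05 was found for 8927 and 9260 genes. The number of genes higher in E11.5 than at day 11 was 2042 without day 11 replicate 1 and 1820 without day 11 replicate 2, and the number higher than at day 14 was 2444 without day 14 replicate 2. In each of the 2 comparisons, 148 genes named by rule passed, of which 137 passed in every fit without 1 library. Kit, strain, cell sorting and age differed together with the group, so no single gene difference here can be assigned to Eed.

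PRC2 genes divided. Eed was higher in E11.5, at 96.3 ± 23.96 CPM, than at day 11 (log2 fold change 2.20, SE 0.33, adjusted p = 9.5e-04) and day 14 (log2 fold change 3.29, SE 0.35, adjusted p = 1.4e-04). Ezh2, at 171 ± 5.30 CPM in E11.5, and Mtf2, an accessory subunit, were higher as well, while Ezh1, the catalytic subunit of resting cells, was lower, at 12.46 ± 4.35 CPM in E11.5 against 45.1 ± 4.75 CPM at day 11. Of 11 genes 4 were higher and 3 lower than at day 11, and 4 higher and 2 lower than at day 14, with the same counts adjusted over the list alone; the list's test did not pass (camera adjusted p = 0.395 and 0.1303). Of 19 genes of Polycomb repressive complex 1, 6 were higher and 3 lower than at day 11, and 5 higher and 4 lower than at day 14, with the same counts adjusted over the list alone. Its median (-0.14 and -0.08) and mean (0.18 and 0.08) differed in sign in both comparisons.

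The developmental regulators Foxg1, Zic1, Foxl2 and Six3 had no count in E11.5 and were higher in Eed-null epithelium. Foxg1, a forebrain regulator, lay at 17.7 ± 2.45 CPM at day 11, at least 182-fold higher, and at 16.97 ± 5.45 CPM at day 14. Zic1, a regulator of the dorsal neural tube, lay at 32.8 ± 14.5 CPM at day 11, at least 338-fold higher, and Foxl2, an ovary regulator, at 22.8 ± 6.37 CPM, at least 235-fold higher. Six3 was at least 127-fold higher at day 11 and at least 432-fold higher at day 14. Sox17, an endoderm and endothelial regulator, lay at 0.0585 ± 0.0828 CPM in E11.5 and 43.2 ± 6.30 CPM at day 11. Of 97 developmental transcription factors 35 were lower in E11.5 than at day 11 and 20 higher, with 36 and 20 adjusted over the list alone; against day 14 the counts were 34 and 26, with 35 and 27 adjusted over the list alone. The list's test did not pass (mean -1.77 and -1.36, camera adjusted p = 0.0602 and 0.149), but against day 11 it passed in the lower direction once a trend on gene span was removed (adjusted p = 0.0189). Without that removal it had adjusted p = 0.626 with an estimated correlation. No wild-type adult RNA library was used here, so these levels have no adult control.

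Among 36 Hox genes 9 were lower and 4 higher in E11.5 than at day 11, with the same counts adjusted over the list alone, and 10 lower and 5 higher than at day 14, with 8 and 4 adjusted over the list alone. The posterior genes Hoxc13 and Hoxc12 were lower in E11.5, Hoxc12 being at least 23.2-fold higher at day 11, while the anterior gene Hoxb2 lay at 20.3 ± 0.811 CPM in E11.5 and 1.13 ± 0.0732 CPM at day 11. Among 7 CDK inhibitors Cdkn2a, Cdkn2b and Cdkn1b were lower in E11.5 and the imprinted Cdkn1c was higher, at 432 ± 91.3 CPM against 8.72 ± 0.286 CPM at day 11 and 6.19 ± 1.04 CPM at day 14. In all, 4 were lower and 1 higher than at day 11, with 5 and 2 adjusted over the list alone, and 5 lower and 2 higher than at day 14, also when adjusted over the list alone. Of 32 Fox genes 7 were higher and 8 lower than at day 11, and 6 higher and 9 lower than at day 14, with the same counts adjusted over the list alone; Foxa1, a pioneer factor of endoderm, lay at 354 ± 36.0 CPM in E11.5 and 28.5 ± 2.44 CPM at day 11.

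Of 25 embryonic growth and imprinted genes 19 were higher in E11.5 than at day 11 and none lower, and 18 were higher than at day 14 and none lower; adjusted over the list alone the counts were 19 and 18, with 1 lower than at day 14. The median was 3.90 against day 11 (camera adjusted p = 3.0e-14, and adjusted p = 0.123 with an estimated correlation) and 4.00 against day 14 (camera adjusted p = 1.3e-13, and adjusted p = 0.117 with an estimated correlation). Dlk1, a Notch-like growth regulator, lay at 437 ± 77.2 CPM in E11.5 and 10.9 ± 1.88 CPM at day 11. Of 39 proliferation genes 21 were higher than at day 11 and 2 lower, and 31 were higher than at day 14 and 2 lower, with the same counts adjusted over the list alone. Their medians were 1.10 (camera adjusted p = 8.9e-05, and adjusted p = 0.588 with an estimated correlation) and 1.76 (camera adjusted p = 2.3e-07, and adjusted p = 0.413 with an estimated correlation). Stmn1, a microtubule regulator of dividing cells, lay at 418 ± 25.5 CPM in E11.5 and 35.4 ± 0.733 CPM at day 11.

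Enterocyte, goblet and Paneth cell lists were lower in E11.5 at the preset correlation only, while enteroendocrine and tuft cell lists did not pass. Of 40 enterocyte genes 34 were lower and 1 higher than at day 11, with 35 and 1 adjusted over the list alone, and 35 lower and 2 higher than at day 14, with 35 and 3 adjusted over the list alone. The medians were -4.89 (camera adjusted p = 1.0e-18, and adjusted p = 0.123 with an estimated correlation) and -5.28, or -5.16 with genes without a count at their bound (camera adjusted p = 1.4e-16, and adjusted p = 0.207 with an estimated correlation). Hnf4a, a regulator of enterocyte genes, lay at 39.6 ± 4.10 CPM in E11.5 and 628 ± 16.9 CPM at day 11. All 14 goblet cell genes were lower than at both days, also when adjusted over the list alone (camera adjusted p = 8.1e-13 and 4.8e-13; adjusted p = 0.123 and adjusted p = 0.197 with an estimated correlation). Atoh1, the regulator of secretory cells, had no count in E11.5 and was at least 491-fold higher at day 11. Of 17 Paneth cell genes 15 were lower and 1 higher than at day 11, and 14 lower than at day 14 (camera adjusted p = 2.7e-11 and 1.8e-11; adjusted p = 0.330 and adjusted p = 0.252 with an estimated correlation). Adjusted over the list alone, 15 and 14 were lower and 1 was higher than at each day. Pla2g2a, a secreted phospholipase that the reference annotates as a transcribed pseudogene, had no count in E11.5 and was at least 1471-fold higher at day 11. Lyz2, of macrophages, lay at 1.36 ± 0.565 CPM in E11.5 and at 40.9 ± 24.2 CPM at day 11.

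Erythroid, neuronal, and pancreas and liver lists were higher in E11.5, whose cells had been sorted for Epcam, and the cells that this RNA came from were not tested. The embryonic globin gene Hbb-y lay at 146 ± 1.81 CPM and had no count in any Eed-null library, and of 6 tested erythroid genes 3 were higher than at day 11 and 4 than at day 14, also when adjusted over the list alone (camera adjusted p = 2.5e-04 and 2.3e-04; adjusted p = 0.233 and adjusted p = 0.235 with an estimated correlation). Of 11 pancreas and liver genes 5 were higher and 1 lower than at day 11, also when adjusted over the list alone, and 6 higher and 1 lower than at day 14, with 8 and 2 adjusted over the list alone (camera adjusted p = 0.0256 and 0.0182; adjusted p = 0.626 and adjusted p = 0.527 with an estimated correlation). Its call against day 11 was lost with the span trend removed (adjusted p = 0.0516). Ptf1a, a pancreas regulator, lay at 17.8 ± 4.48 CPM in E11.5, at least 129-fold above day 11. Of 24 neuronal genes 10 were higher and 2 lower than at each day, also when adjusted over the list alone (camera adjusted p = 0.0164 and 0.0182; adjusted p = 0.330 and adjusted p = 0.249 with an estimated correlation).

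**Figure D3:**
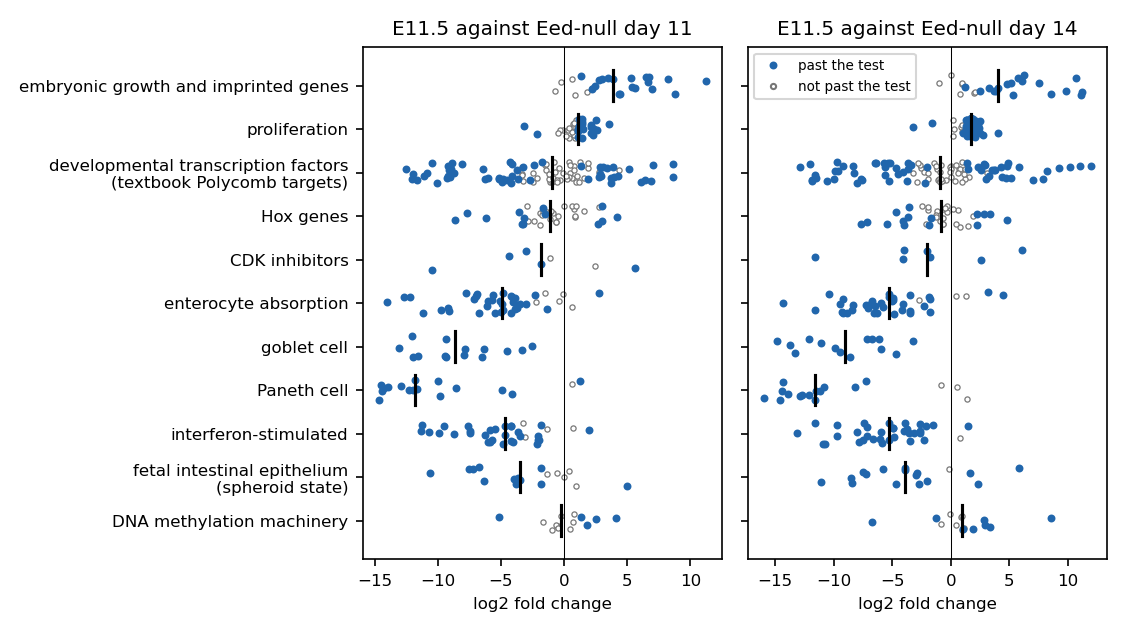
Log2 fold change of E11.5 over Eed-null day 11 and over day 14 for each member of 11 lists, with a filled point for an adjusted p under 0.05 and at least a 2-fold change, an open point otherwise and a black line at the median. Embryonic growth and imprinted genes have medians of 3.90 and 4.00, and goblet cell genes of -8.67 and -9.05.

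Whether day 14 stood nearer to the embryonic state than day 11 was asked with genes that parted E11.5 from the mean of both days. The 3939 genes higher in E11.5 lay lower at day 14 than at day 11 by a median difference of -0.247 from other genes, with 37 rises and 107 falls (camera p = 9.1e-04, and p = 0.0806 with an estimated correlation). The 4043 genes lower in E11.5 lay higher at day 14, by 0.291, with 132 rises and 25 falls (camera p = 1.7e-04, and p = 0.162 with an estimated correlation). In 30 simulated data sets without change the differences ran from -0.001 to 0.019 and from -0.021 to 0.025. These ranges are narrower than those seen when 1 library was left out, so they do not cover the spread between libraries. At the preset correlation the medians of these sets thus lay farther from E11.5 at day 14. Because the sets were chosen on the mean of both days, they can hold genes that parted from E11.5 at day 14 alone. Such genes count towards this difference, and those that parted at day 11 alone count against it. The simulated data, which held no change, did not include them. The comparison therefore cannot part a shift away from E11.5 from a difference in counting at day 14. In fits chosen only after the result was seen, without genes that have a named copy, ribosomal protein genes and the listed genes of non-epithelial cells, the differences were -0.239 and 0.294, and -0.306 and 0.318 with the span trend removed as well. Other genes of non-epithelial cells were left in these sets. Without 1 library the differences ranged from -0.333 to -0.0759, and from 0.266 to 0.435. The first was -0.113 without E11.5 replicate 2, -0.096 without day 11 replicate 1, -0.076 without day 11 replicate 2 and -0.089 without day 14 replicate 2.

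DNA methylation was compared between the embryonic, adult and macrophage libraries to ask where adult epithelium keeps the low-methylated DNA of the embryo. The mean methylation level of CpG sites was 75.12% in E12.5 (SD over 19 autosomes 1.83), 69.64% in E16.5 (SD 1.57), 69.60% in adult epithelium (SD 1.84) and 77.85% in macrophages (SD 1.26). From E12.5 to E16.5, 93033 of 1169867 tiles of 1000 bp (7.95%) were lower by at least 30 points and 22416 (1.92%) were higher. From E16.5 to adult, 1.44% of 1335150 tiles were lower and 2.27% higher. Read from every other site in 541438 tiles, 1.73% were lower and 2.36% higher, against 2.67% and 2.68% between alternate sites within the E16.5 library and 0.73% and 0.75% within the adult library. Macrophage DNA was higher than adult DNA in 138673 of 1352221 tiles (10.26%) and lower in 1.93%. The numbers of tiles depend on the threshold and on the sites per tile, and with 1 library per condition they compare libraries.

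**Figure D4:**
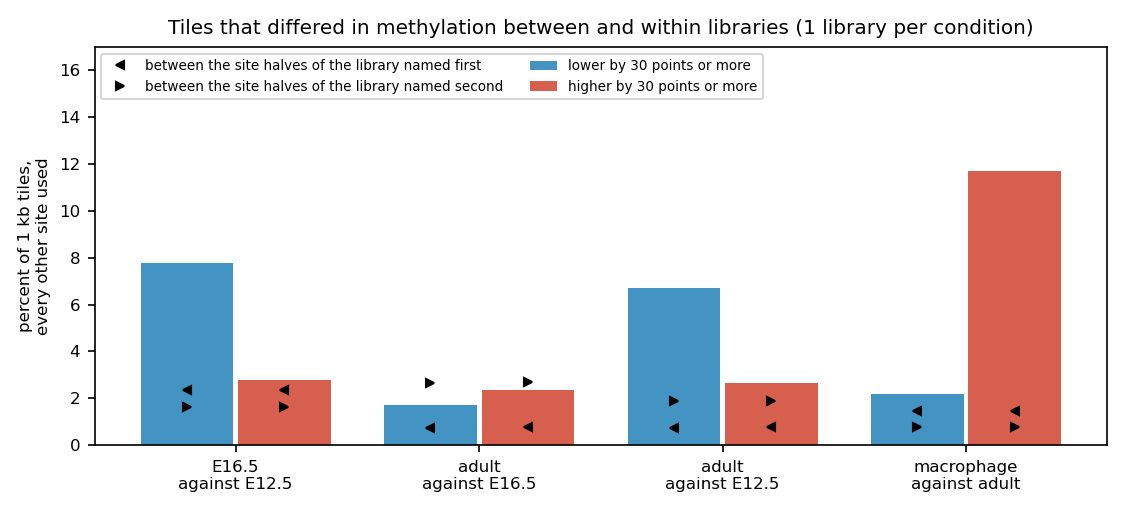
Percent of 1000 bp tiles that were lower or higher by at least 30 points between pairs of libraries, read from every other site, as bars, with black triangles for the same measure between alternate sites within each library. The bars for E16.5 minus E12.5 stand at 7.79% lower and 2.76% higher, against 1.62% to 2.36% within the libraries.

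Single tiles changed almost from end to end of the scale. On mm9 chromosome 19, the tile from 11306000 to 11306999 measured 97.7% in E12.5 over 11 sites, 2.1% in E16.5 over 8 sites and 1.0% in adult epithelium over 11 sites, and 88.1% in macrophages. On the same chromosome the tile from 55417000 to 55417999 went from 98.8% in E12.5 to 4.0% in E16.5 and 2.3% in adult epithelium over 15 to 20 sites. In the other direction, the tile from 112513000 to 112513999 on chromosome 12 measured 0.0% in E12.5 over 89 sites, 91.7% in E16.5, 95.0% in adult epithelium and 3.5% in macrophages. On chromosome 12 the tile from 58651000 to 58651999 went from 1.2% to 91.7% and 93.2%, with 9.6% in macrophages. The tile on chromosome 16 from 91523000 to 91523999 measured 92.2% in adult epithelium and 0.0% in macrophages.

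Low-methylated regions, which are CpG-poor and often mark enhancers, numbered 94612 in E12.5, 157303 in E16.5, 175239 in adult epithelium and 75561 in macrophages. Of 51021 such E12.5 regions that were methylated in macrophages, 28478 (55.82%, Clopper-Pearson interval 55.38 to 56.25, SD over autosomes 2.58) were under 50% in adult epithelium and 61.34% in E16.5. Regions shifted by 20000 bp were under 50% in adult epithelium in 11.70% (Clopper-Pearson interval 11.33 to 12.08). The mirror set of macrophage regions that were methylated at E12.5 gave 28.90% (Clopper-Pearson interval 28.39 to 29.41). Of 76236 adult regions methylated in macrophages, 36.35% were under 50% at E12.5 and 83.97% at E16.5. The share depends on the level called low, being 34.01% under 30%. The numbers of low-methylated regions compare libraries of unlike coverage. In the adult library 76.5% of sites had both positions of the CpG measured, against 37.8% to 38.8% in the other libraries. Regions were not called on matched sites. Low regions called from the first position of each CpG alone stayed under 50% on the second position in 70.3% of E12.5 regions. Some E12.5 calls may thus not hold within their own library. Such regions could lower the share kept low in adult epithelium.

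Of 30639 E12.5 regions at 80% or more in macrophages, 6817 were under 20% in adult epithelium, whatever their E12.5 level under 50%, and 5055 were at 80% or more. Among those under 20%, the region on mm9 chromosome 9 from 115264677 to 115266704 measured 7.2% in E12.5, 0.0% in E16.5, 7.1% in adult epithelium and 91.5% in macrophages over 23 to 34 sites. A region on chromosome 4 from 128466858 to 128467985 measured 8.4%, 19.7%, 10.8% and 90.8% in the same order. Among those at 80% or more, the region on chromosome 19 from 32941270 to 32942243 measured 12.7% in E12.5, 97.8% in E16.5, 92.0% in adult epithelium and 95.7% in macrophages. On chromosome 4 the region from 114321190 to 114321789 measured 8.5% in E12.5, 31.5% in E16.5 and 85.3% in adult epithelium.

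**Figure D5:**
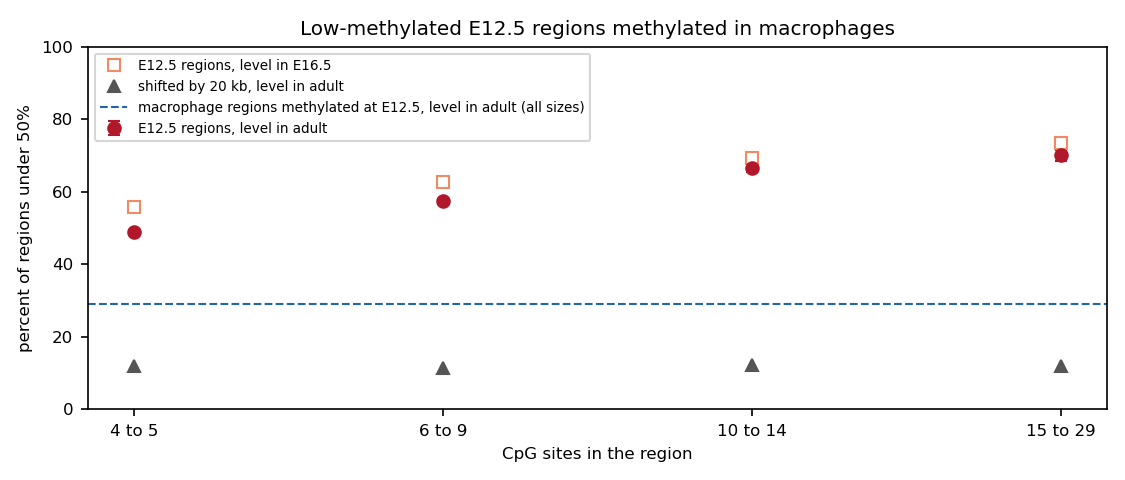
Percent of low-methylated E12.5 regions, methylated in macrophages, that were under 50% in adult epithelium (with Clopper-Pearson 95% interval) and in E16.5, by number of CpG sites, with shifted regions and a dashed line for the mirror set. The adult share runs from 48.9% at 4 to 5 sites to 70.1% at 15 to 29 sites, and the shifted share from 11.3% to 12.1%.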

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

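The tests of explanations in this part were chosen only after the result was seen. Mitochondrial CpG positions had mean levels of 74.31% in the E12.5 library, 69.03% in E16.5, 62.29% in adult epithelium and 75.28% in macrophages. They are given here because a signal appeared in data that no comparison reported on, without a control sample to set it against. In every library the first position of a pair had a higher mean than the second, in E16.5 77.93% against 59.51%. How completely unmethylated cytosines were converted was not checked. These levels are therefore not shown to be methylation of mitochondrial DNA.

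Genes with a named pseudogene copy, ribosomal protein genes among them, were higher at day 14 than at day 11, with 92 of 320 risen and 2 fallen. With a trend on gene span removed, their median log2 fold change still exceeded that of other genes by 0.92, so such a trend is not the whole cause. Of annotated pseudogenes, 10 stood at 10 CPM or more at day 14 and under 1 CPM at day 11, against 0 in the other direction, so reads shared with processed pseudogenes may have been counted differently in the day 14 libraries. Of the 10 ribosomal protein genes without a named copy 1 rose, with a median of 1.21. The list passed without genes that have one (camera adjusted p = 3.3e-06), while all 41 had adjusted p = 0.926 with an estimated correlation. Sec61g and Sumo2, which rose from almost no counts, have no named copy either. Copies under other names were not counted, so these 10 genes cannot part shared reads from a biological rise. Whether such reads are the whole cause, and a biological rise of ribosomal protein RNA, stay open.

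Of 16 secreted antimicrobial and acute response genes 3 rose from day 11 to day 14, and 10 adjusted over the list alone (camera adjusted p = 1.1e-05, and adjusted p = 0.926 with an estimated correlation). With the span trend removed their median exceeded that of other genes by 2.06, the leukocyte list had a median of -2.15, and goblet and Paneth genes outside the list had an upper quartile of 1.25. These values argue against a span trend as the whole cause, against more leukocytes at day 14 and against a larger share of both secretory cell types as large as the list's change. A difference in counting at day 14, raised above for genes with pseudogene copies, was not tested for this list. No tested member has a named copy, but reads shared with other genes would not be seen that way. With 0 wild-type adult count columns used beside the days, more time without Eed rather than another difference between the libraries of the 2 days cannot be told apart, and Xist and Y-linked RNA did differ between the days. A response of the epithelium to longer Eed loss is a hypothesis that these data could not test.

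Low-methylated E12.5 regions stayed under 50% in adult epithelium more often than shifted regions or the mirror set. Levels read from few sites are argued against by the 70.1% found in regions of 15 to 29 sites. Lower methylation of the adult library as a whole is argued against by 11.70% among shifted regions. A tendency of regions low in any tissue to be low in adult epithelium was present, at 28.90% in the mirror set against 8.69% when that set was shifted, but as the whole cause it is argued against by the 55.82% of E12.5 regions. Low methylation kept from the embryonic gut may account for the excess, as a hypothesis found and tested on the same data, with 1 library per condition and unknown depth.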

How the results depend on the processing

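The fits with a span trend removed, without genes with a named pseudogene copy or of ribosomal protein and non-epithelial lists, and with other numbers of sites were chosen only after the data were seen. With 2 libraries per group, a fit without 1 library takes the lone library to vary like the other groups. No called direction of a named gene or a gene list was reversed under the alternatives that were run. For day 14 against day 11, 429 rises and 379 falls became 700 and 671 without a filter on low counts, 1354 and 1231 with DESeq2, 260 and 206 without genes with a named pseudogene copy and 164 and 72 with the span trend removed as well; falls were 214 with all 6 libraries in 1 fit and 157 with the span trend removed alone. The cause was not tested, except that fewer genes are tested without copies. With the replicate number as a block, which pairs libraries by number although deviations correlated at 0.081 between the days, falls were 825. Without 1 library, rises ranged from 210 to 1194 and falls from 49 to 1186. Against day 11, genes higher in E11.5 ranged from 1820 to 3256 and lower from 2865 to 4186, and against day 14 they ranged from 2444 to 3621 and from 3462 to 4270. With an estimated correlation 0 lists passed for day 14 against day 11, 0 for E11.5 against day 11 and 0 for E11.5 against day 14. That form of the test had only 2 or 3 residual degrees of freedom, so few lists could pass it, and other causes were not tested. With an estimated correlation the differences -0.247 and 0.291 of the genes that part E11.5 from adult cells did not pass. Without 1 library these differences ranged from -0.333 to -0.0759 and from 0.266 to 0.435.

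Tile counts are given in the order E16.5 lower and higher than E12.5, adult lower and higher than E16.5, adult lower and higher than E12.5, and macrophage lower and higher than adult. At 20 points they were 200276, 60605, 78652, 91228, 208828, 64440, 59086 and 290118, and at 50 points 21245, 3361, 1087, 2853, 18082, 3881, 5906 and 39251, as a looser or stricter limit must give. With at least 3 sites per tile they were 177436, 46003, 57377, 74855, 163375, 46955, 53909 and 215220, and with at least 10 sites 25604, 7602, 2656, 4031, 26854, 8819, 9039 and 53534; the cause was not tested. With tiles of 2000 bp the counts, from E16.5 higher than E12.5 on, were 9282, 12144, 17949, 55185, 10077, 12395 and 79756. With sites measured in all 4 libraries, adult was lower than E16.5 in 7316 tiles, higher in 18282 and lower than E12.5 in 56551; the cause was not tested.

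Low-methylated regions in E12.5, E16.5, adult and macrophage numbered 49493, 79241, 89867 and 39054 with at least 6 sites, 49731, 78712, 81989 and 43774 under 30%, and 20139, 31377, 36406 and 16163 with at least 10 sites, as stricter limits give. The adult share of low regions was 34.0% under 30%, 71.45% for E16.5 regions, 49.7% with a macrophage level of 80% or more, 66.2% with at least 8 measured sites per library and 67.9% for regions of at least 10 sites; the cause was not tested. Minimums of 5 and 10 reads, thinning and other minimums of calls were not run, because the files hold no read numbers, and list tests were not repeated without single libraries. Of the comparisons of named genes with other settings, 1760 of 2047 kept their side of the threshold for day 14 against day 11, 2273 of 2313 for E11.5 against day 11 and 2269 of 2314 for E11.5 against day 14. Goblet, stem cell, interferon and DNA methylation lists did not pass for day 14 against day 11 once the span trend was removed. With it removed the Fox list passed (adjusted p = 0.0325), and with the replicate number as a block, which pairs libraries by number, the fetal spheroid list passed (adjusted p = 0.0307). For E11.5 against day 11, removing the span trend made the Hox (adjusted p = 0.0452), developmental factor (0.0189), tuft cell (0.0290), ribosomal protein (0.00433) and lipid synthesis lists (0.0442) pass, each in the lower direction, and ended the call of the pancreas and liver list (0.0516). With the block the tuft cell (0.0371) and lipid synthesis lists (0.0344) passed against day 11, and the lipid synthesis list no longer passed against day 14 (0.0577). With an estimated correlation, and neither block nor removal, none of these lists passed. The cause of these changes was not tested. At 2 libraries per group most 2-fold changes could not be found.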

Other observations

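No tests of explanations were made in this part, and genes named here outside the fixed rule were chosen only after the values were seen. Lists of p53 targets, interferon-stimulated genes and antimicrobials were lower in E11.5 at the preset correlation only. Of 20 p53 target and apoptosis genes 14 were lower in E11.5 than at day 11, and 12 lower and 2 higher than at day 14, also when adjusted over the list alone (camera adjusted p = 1.6e-06 and 8.6e-06; adjusted p = 0.275 and adjusted p = 0.249 with an estimated correlation). Zmat3, a p53 target that regulates splicing, lay at 8.06 ± 0.721 CPM in E11.5 and 188 ± 5.43 CPM at day 11. Of 35 interferon-stimulated genes 29 were lower and 1 higher than at day 11, with 32 and 1 adjusted over the list alone, and 33 lower and 1 higher than at day 14, also when adjusted over the list alone (camera adjusted p = 7.8e-11 and 1.6e-11; adjusted p = 0.588 and adjusted p = 0.490 with an estimated correlation). Of 7 genes of major histocompatibility complex (MHC) class II 6 were lower than at each day (camera adjusted p = 0.00394 and 0.00501; adjusted p = 0.626 and adjusted p = 0.573 with an estimated correlation). Of 17 secreted antimicrobials 13 were lower and 1 higher than at day 11, and 14 lower than at day 14 (camera adjusted p = 5.4e-05 and 3.5e-07; adjusted p = 0.330 and adjusted p = 0.249 with an estimated correlation). Counts for the MHC and antimicrobial lists were the same adjusted over the list alone.

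Fatty acid oxidation and xenobiotic lists were lower in E11.5 at the preset correlation only. Of 20 genes of fatty acid oxidation 14 were lower than at day 11 and 16 than at day 14, with 14 and 17 adjusted over the list alone (camera adjusted p = 6.0e-05 and 2.3e-07; adjusted p = 0.363 and adjusted p = 0.249 with an estimated correlation). Cpt1a, which lets fatty acids into mitochondria, lay at 4.77 ± 2.98 CPM in E11.5 and 315 ± 16.6 CPM at day 11. Of 22 xenobiotic and bile acid genes 17 were lower and 1 higher than at day 11, and 16 lower and 1 higher than at day 14, also when adjusted over the list alone (camera adjusted p = 6.0e-08 and 3.6e-07; adjusted p = 0.275 and adjusted p = 0.249 with an estimated correlation). Of 22 lipid synthesis genes 10 were lower than at day 11, and 13 lower and 1 higher than at day 14, also when adjusted over the list alone (camera adjusted p = 0.0706 and 0.0415, the latter with adjusted p = 0.622 with an estimated correlation). With the replicate number as a block, which pairs libraries by number, this list passed against day 11 (adjusted p = 0.0344) and did not against day 14 (adjusted p = 0.0577), and with the span trend removed it passed against day 11 (adjusted p = 0.0442). Without the block or the removal, against day 11 it had adjusted p = 0.626 with an estimated correlation. Of 17 genes of the fetal spheroid state 11 were lower and 1 higher than at day 11, and 13 lower and 3 higher than at day 14, also when adjusted over the list alone (camera adjusted p = 0.00549 and 0.00396; adjusted p = 0.626 and adjusted p = 0.622 with an estimated correlation). Of 20 stem cell genes 12 were lower and 3 higher than at day 11 (camera adjusted p = 0.00373, and adjusted p = 0.626 with an estimated correlation), and 9 lower and 4 higher than at day 14 (camera adjusted p = 0.106), also when adjusted over the list alone. None of 41 ribosomal protein genes was higher in E11.5 with edgeR. Against day 11, 3 were lower, with none adjusted over the list alone (camera adjusted p = 0.552, 0.00433 with the span trend removed, and without the removal adjusted p = 0.9497 with an estimated correlation). Against day 14, 35 were lower, with 36 adjusted over the list alone (camera adjusted p = 3.4e-08, and adjusted p = 0.573 with an estimated correlation). Without the 31 genes that have a named pseudogene copy the list still passed against day 14 (camera adjusted p = 0.00555). Of annotated pseudogenes, 11 stood at 10 CPM or more at day 14 and under 1 CPM in E11.5, against 1 in the other direction. A difference in counting at day 14 can therefore not be told apart here from a difference in ribosomal protein RNA.

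Of 19 mesenchyme genes 6 were higher and 2 lower in E11.5 than at day 11 (camera adjusted p = 0.0924), and 16 higher and 2 lower than at day 14, with 17 and 2 adjusted over the list alone (camera adjusted p = 1.3e-05, and adjusted p = 0.490 with an estimated correlation). Against day 11 the endothelium (6 of 13 lower, 7 adjusted over the list alone), leukocyte (9 of 13 lower, 10 adjusted over the list alone) and macrophage lists (12 of 18 lower, also when adjusted over the list alone) passed in the lower direction, with camera adjusted p = 0.0256, 0.0129 and 0.00533 and adjusted p = 0.626 with an estimated correlation for each. Against day 14 these 3 lists did not pass (camera adjusted p = 0.813, 0.285 and 0.832), and for macrophage genes the median (0.82) and mean (-0.46) differed in sign, as the endothelium median (0.25) did from the lower direction of its test. The tuft cell (camera adjusted p = 0.0754 and 0.140), smooth muscle (0.820 and 0.943), enteroendocrine (0.837 and 0.874), dissociation response (0.837 and 0.606), DNA methylation (0.552 and 0.0604) gut identity (0.480 and 0.558), Hox (0.290 and 0.280), CDK inhibitor (0.318 and 0.234), Fox (0.460 and 0.716) and PRC1 lists (0.460 and 0.716) did not pass against either day. Against day 11 the tuft cell list passed with the span trend removed (adjusted p = 0.0290) and with the block (adjusted p = 0.0371), and the Hox list with the span trend removed (adjusted p = 0.0452). Without these changes they had adjusted p = 0.626 and adjusted p = 0.805 with an estimated correlation. Median and mean differed in sign against day 11 for the smooth muscle, dissociation response, DNA methylation and identity lists, and against day 14 for the enteroendocrine and identity lists. Between day 14 and day 11 the Hox (camera adjusted p = 0.796), PRC1 (0.771), developmental factor (0.528), CDK inhibitor (0.569), Fox (0.262), embryonic growth (0.466), fetal spheroid (0.346), enterocyte (0.733), Paneth (0.268), enteroendocrine (0.916), tuft (0.771), p53 (0.947), MHC class II (0.796), dissociation response (0.215), identity (0.916), neuronal (0.947), smooth muscle (0.853), pancreas and liver (0.787), lipid synthesis (0.559) and xenobiotic lists (0.916) did not pass, nor did PRC2 (0.231). Among these the Hox median (0.11) and mean (-0.05) differed in sign, as did the neuronal and xenobiotic ones, and the enteroendocrine median (-0.16) differed from the upward direction of its test.

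Rn45s, the precursor of ribosomal RNA, lay at 9329 ± 4184 CPM in E11.5, 2585 ± 712 CPM at day 11 and 836 ± 324 CPM at day 14. Gm17821 lay at 831 ± 66.1 CPM at day 14 and had no count at day 11 or in E11.5. Xist lay at 131 ± 29.8 CPM and Ddx3y at 36.2 ± 7.995 CPM in E11.5. Vil1, of the brush border, lay at 34.6 ± 4.72 CPM in E11.5 and 1049.5 ± 126 CPM at day 11. Unmethylated regions numbered 16564 in E12.5, 16886 in E16.5, 18361 in adult epithelium and 15552 in macrophages, and 98.4% of the E12.5 ones were under 50% in adult epithelium and 96.4% in macrophages. Low regions called from the first position of each CpG stayed under 50% on the second position in 70.3% of E12.5, 74.9% of E16.5, 81.6% of adult and 73.9% of macrophage regions. The strands of these positions are inferred from adjacency, as the tables do not give them.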
